A study of Mus musculus with 2 samples.

How the data were processed

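HL-1 cells were grown to their highest density, and 1 library was made per antibody, against Srf and against acetylated histone H3, by Illumina's procedure and sequenced on a Genome Analyzer, per the labels' protocols. The deposited lists give an identifier, chromosome, start and end for each called peak, per the file headers, with no score, height, p-value or read count. The genome build was mm9, per the submitters' processing notes. The aligner, the peak caller, any input control and any filter on peaks are not given in the sources used here. Whether positions count from 0 or from 1 is not stated, which can shift a gap by 1 bp, so leaving out touching ends was tried as an alternative. The depth of either library is unknown, and the precision given is that of the number of peaks.

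Peaks were used as called. An Srf peak counted as shared when it and an H3ac peak had at least 1 bp in common. Gaps were taken between nearest edges. Shares have exact Clopper-Pearson intervals (95%). The interval of the median gap was read from the sorted gaps at binomial ranks. Cover ratios and the difference in median offset have bootstrap intervals from 1000 resamples. Chance came from 1000 shifts, in each of which all Srf peaks of a chromosome moved by the same random distance and wrapped around its span, from the first to the last peak of both lists. Uniform placement, and individual moves of each Srf peak by 10000 to 100000 bp in either direction, were run beside it. Intervals of a fold divide the bounds of the observed share by the mean of the displaced peaks. Median widths were compared by two-sided permutation tests with 100000 resamples over peaks, which are not replicates. Cover around Srf midpoints was read every 25 bp out to 3000 bp. Narrow H3ac peaks were those under 350 bp.

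Before the data were examined, the overlap, distance and width comparisons, their tests and most alternatives were fixed. A peak score was planned for ranking, and width took its place because the lists hold no score. The rule for naming items took the 10 widest Srf peaks, the 5 widest H3ac peaks and the 3 regions of 100 kb with the most Srf peaks. The 5 H3ac peaks with the highest score were part of the rule and are not given. The individual moves, the thinning of the H3ac list, the cover profile, the comparison of chromosomes, the bins of 1 Mb with at least 8 Srf peaks, the windows from 2.9 to 3.1 Mb and the settings of each were chosen after seeing the data.

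In the gene table at hand, 31 Srf and 91 H3ac peaks began past the last gene of their chromosome, which by itself shows no mismatch of assembly. That table followed assembly GRCm38.p6, not mm9. No gene, transcription start site or sequence motif was therefore assigned to any peak, and the planned comparisons of start sites, of the CArG box (the sequence motif bound by Srf) and of gene lists were not made. Steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap step was tested on simulated lists of 2190 Srf peaks. With uniform positions it found 8 overlaps where shifts gave 6.585, and with 500 planted overlaps it found 506, which was 79.8 times the shifted mean.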

Results

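Binding sites of Srf (serum response factor, a transcription factor of muscle and growth-response genes) and regions of acetylated histone H3 (H3ac, a chromatin mark of active promoters and enhancers) were mapped by chromatin immunoprecipitation and sequencing in HL-1 cells, a contracting mouse cell line derived from atrial cardiomyocytes. There was 1 library per antibody, so no value has a replicate check and no test compares conditions. The Srf list held 2190 peaks, which covered 0.45 Mb. The H3ac list held 10486 peaks, which covered 4.05 Mb. Both lists give the position of each peak without a score or read count, so the read depth of either library is unknown. Srf peaks had a median width of 179 bp (quartiles 129 and 232.75 bp, range 99 to 3812 bp). H3ac peaks had a similar median, 185 bp, but a longer tail: 10.9% were 1000 bp or wider, against 0.41% of Srf peaks. All positions are given in mm9, as the lists give them.

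The first comparison asked how often Srf-bound regions and acetylated regions of the same cells coincide. Of the 2190 Srf peaks, 606 overlapped an H3ac peak by at least 1 bp, which is 27.7% (exact 95% interval 25.8% to 29.6%). A further 622 Srf peaks (28.4%, interval 26.5% to 30.3%) did not overlap an H3ac peak but had one within 500 bp. The converse share was small: 551 of the 10486 H3ac peaks, or 5.25% (4.84% to 5.70%), overlapped an Srf peak. When all Srf peaks of a chromosome were shifted together along it, a mean of 0.307% overlapped H3ac peaks, and none of 1000 shifts reached the observed share (the highest gave 1.83%). The observed Srf share was 90.1 times the shifted mean (84.0 to 96.3, from the counting interval of the share), and the H3ac share was 87.1 times its own shifted mean. Srf peaks moved individually by 10000 to 100000 bp, which keeps them in their neighbourhoods, overlapped H3ac peaks in 1.81% of cases (highest of 1000 moves 2.74%), so the fold was 15.3 (14.2 to 16.3) against this closer background. Required cover of at least 50% of the Srf peak lowered the share to 15.2%, and the H3ac peaks at or above their median width gave 17.9%. Intervals here and below cover counting error only and treat peaks as independent, although they cluster along the genome. Displaced peaks do not keep pileups of reads that both libraries may share, so these folds do not separate Srf binding at acetylated regions from such pileups.

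The distance between the marks shows where Srf peaks without overlap lay. The median gap from an Srf peak to the nearest H3ac peak was 248.5 bp (95% interval from binomial ranks 210 to 317 bp). Within 500 bp of an H3ac peak lay 1228 Srf peaks, or 56.1% (54.0% to 58.2%), against 4.04% of the individually moved peaks and 0.786% of the shifted ones. Widening the gap to 1000 bp added few, for a total of 60.5%, and 72.6% lay within 10000 bp. Within 100000 bp lay 93.4%, against 92.8% of the moved peaks, which such moves keep close by construction, and 37.5% of the shifted ones. The remaining 145 Srf peaks (6.62%, interval 5.62% to 7.74%) had no H3ac peak within 100000 bp. The median gap of the moved peaks averaged 20493.5 bp and never fell under 18608 bp. The gap depends on the H3ac peaks counted: to those at or above the median width it was 17524 bp, with 27.8% of Srf peaks within 500 bp. Measured between midpoints, the median distance was 532.25 bp.

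**Figure D1:**
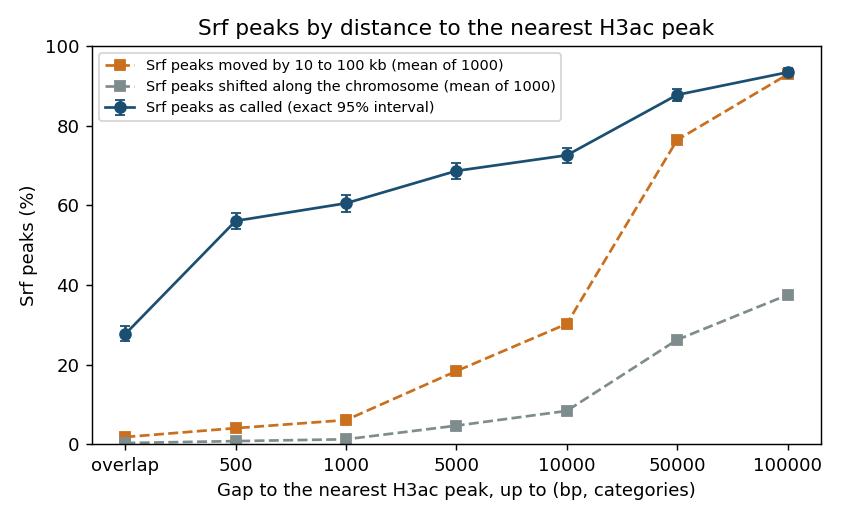
Share of the 2190 Srf peaks (%, vertical axis) that overlapped an H3ac peak or lay within the stated gap of one (bp, equally spaced categories), with exact 95% intervals, beside the mean of 1000 shifts along the chromosome and of 1000 individual moves of 10000 to 100000 bp. The Srf peaks as called start at 27.7% for overlap and reach 56.1% at 500 bp, where the moved peaks are at 4.04%; at 100000 bp the moved peaks are at 92.8% by the limit of the moves.

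Around Srf peaks, H3ac peaks were laid out in a narrow band with a shallow dip at the midpoint. At Srf midpoints, 16.8% of Srf peaks lay under an H3ac peak. The share was higher at 250 bp upstream and downstream in genome order, 19.6% and 18.9%, and fell to 3.17% at 2000 bp. Moved Srf peaks gave a mean of 1.27% over the same window. Averaged over 200 to 300 bp from the midpoint, H3ac cover was 1.14 times that within 50 bp (bootstrap interval 1.07 to 1.23). Both windows were chosen after seeing the data, which the bootstrap intervals here do not account for. The ratio was 1.09 (0.98 to 1.20) at the narrower Srf peaks and 0.937 (0.816 to 1.07) in the megabases densest in Srf peaks, both intervals including 1, and differences between these subsets were not tested. Without those megabases and the chromosome starts, 1585 Srf peaks gave a ratio of 1.32 (1.19 to 1.46).

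**Figure D2:**
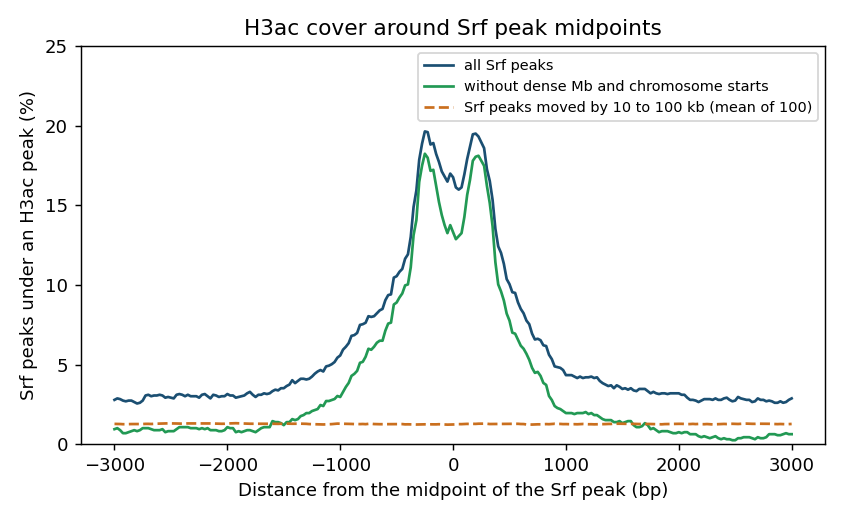
Share of Srf peaks (%, vertical axis) whose surroundings were under an H3ac peak at each distance from the Srf midpoint (bp), for all Srf peaks, for those outside dense megabases and chromosome starts, and for Srf peaks moved by 10000 to 100000 bp (mean of 100 moves). Cover for all Srf peaks was 16.8% at the midpoint and 19.6% and 18.9% at 250 bp on its sides, and the moved peaks stayed near 1.27%.

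The widest peaks of each list were examined singly. All 10 of the widest Srf peaks overlapped an H3ac peak (exact interval from 69.2%), though some of these H3ac peaks were as narrow as 41, 42 or 81 bp. Without scores or an input library, pileups of reads at repeated sequence were not told apart from binding at these peaks. The widest spanned chromosome 1 from 24618287 to 24622099 (3812 bp), and 2 H3ac peaks lay on it, the wider of them 81 bp. On chromosome 17 an Srf peak from 39979928 to 39983732 (3804 bp) held an H3ac peak of only 42 bp, and a neighbour from 39984647 to 39985880 (1233 bp) held one of 465 bp. The third by width lay on chromosome 4 from 79649110 to 79651165 (2055 bp), with an H3ac peak of 679 bp. On chromosome 2, Srf peaks from 22443993 to 22445349 (1356 bp) and from 98506317 to 98507561 (1244 bp) overlapped H3ac peaks of 146 and 41 bp. Another 3 lay on chromosome 11, from 3042733 to 3044417, from 3052332 to 3053547 and from 3062325 to 3063329, with H3ac peaks of 7539, 580 and 516 bp. The last of the 10 was on chromosome 12 from 40763839 to 40764838 (999 bp), with an H3ac peak of 161 bp.

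Of the 5 widest H3ac peaks, 2 overlapped Srf peaks. The widest, on chromosome 11 from 3041435 to 3048974 (7539 bp), carried 13 Srf peaks. One on chromosome 14 from 26275907 to 26281823 (5916 bp) carried 2 Srf peaks. The peak on chromosome 12 from 8303578 to 8309594 (6016 bp) had its nearest Srf peak 28829 bp away. Those on chromosome 7 from 108074333 to 108080866 (6533 bp) and on chromosome 3 from 137727851 to 137733808 (5957 bp) lay 480546 and 2626379 bp from any Srf peak.

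Across each list, peaks that overlapped the other mark were wider. Srf peaks with an H3ac overlap had a median width of 197 bp, against 173 bp for the 1584 without. H3ac peaks with an Srf overlap had a median width of 224 bp, against 184 bp. Overlap was most frequent among the 548 Srf peaks of 233 bp or more, of which 39.8% (35.66% to 44.02%) overlapped H3ac, against 22.1% to 24.6% in the 3 classes of narrower peaks (99 to 129, 130 to 179 and 180 to 232 bp). H3ac peaks of 1000 bp or more overlapped Srf in 10.7% of cases (9.01% to 12.7%), and narrower ones in 4.58% (4.17% to 5.03%). Within 500 bp these classes were nearly level, at 11.4% and 10.5%. Each difference in median had a permutation p = 1e-05 (two-sided, the smallest 100000 resamples can give, also after Benjamini-Hochberg adjustment over the 2 tests), which describes these lists only. Wide peaks meet others more often by length alone: moved Srf peaks gave an average difference of 22.4 bp in Srf width (-10 to 64 bp) beside the observed 24 bp. Moved peaks gave an average of 589 bp in H3ac width (114 to 1183 bp) beside the observed 40 bp, which lay below what length alone gave. The Srf difference was 14.5 bp without dense megabases and chromosome starts and 10 bp with gaps up to 1000 bp. Both differences changed sign with the rule for sharing: the Srf difference was -12.5 bp (permutation p = 0.0414) with cover of at least 50% of the Srf peak, and the H3ac difference was -8 bp (permutation p = 0.041) with gaps up to 1000 bp.

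Along the genome, Srf peaks were more crowded than H3ac peaks: their 34 densest bins of 1 Mb held 27.4% of them, and the 34 densest bins of H3ac lists thinned at random to 2190 peaks held 13.0% on average (highest of 1000 draws 14.5%). Past the first 4 Mb, the 29 densest bins held 21.6% of Srf peaks and 11.7% of thinned H3ac peaks (highest 13.1%). The 100-kb region with the most was chromosome 11 from 3 to 3.1 Mb, which held 92 Srf peaks (3000365 to 3100027) and 23 H3ac peaks, and 50 of these Srf peaks overlapped H3ac. Next came chromosome 9 from 3 to 3.1 Mb, with 41 Srf peaks (3000376 to 3038301) but 5 H3ac peaks. The X chromosome followed from 166.4 to 166.5 Mb, with 20 Srf peaks (166413761 to 166437344) and 10 H3ac peaks. These 3 regions held 6.99% of all Srf peaks and 0.362% of H3ac peaks. Random uniform placement of the Srf peaks put at most 6 into any 100-kb region.

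Chromosome 8 carried 309 Srf peaks, 14.1% of the list, beside 800 H3ac peaks, 7.63% of theirs. Its 0.386 Srf peaks per H3ac peak was 1.99 times (1.73 to 2.29) the 0.194 of the other chromosomes. It was the highest such value of any chromosome and was picked after seeing the data, which the interval does not account for. Its dense stretches were a block from 122 to 130 Mb with 175 Srf and 280 H3ac peaks, and a smaller one from 107 to 110 Mb with 44 Srf and 73 H3ac peaks. Without these blocks chromosome 8 had 0.201 Srf peaks per H3ac peak. This was 1.04 times (0.822 to 1.31) the value of the other chromosomes, which kept their own dense bins and starts. The ratio was 1.23 times (0.976 to 1.55) when dense megabases and chromosome starts were left out everywhere. Leaving out bins picked for their many Srf peaks tends to lower such a ratio by selection. In the larger block 40% of the Srf peaks (32.7% to 47.7%) overlapped H3ac. Other dense stretches were chromosome 9 from 44 to 45 Mb (32 Srf and 38 H3ac peaks), chromosome 14 from 21 to 23 Mb (24 and 34) and from 26 to 27 Mb (19 and 44), and chromosome 12 from 8 to 9 Mb (14 and 27). In all, 29 megabase bins past the first 4 Mb of a chromosome held at least 8 Srf peaks each and together 432. H3ac peaks were denser there too, at 28.4 per Mb against 3.77 in other bins past 4 Mb. Chance overlap was not worked out for each class of bins, so the shares below are not adjusted for this density. Overlap with H3ac was 38.4% (33.8% to 43.2%) in the dense bins, against 23.7% (21.6% to 25.8%) for the 1564 Srf peaks of other bins past 4 Mb. Within the first 4 Mb it was 36.1% of 194 Srf peaks, and 19.6% (12.4% to 28.6%) of the 102 outside the region of chromosome 11 from 3 to 3.1 Mb. By chromosome, the overlap ranged from 8.22% of the 73 Srf peaks on chromosome 3 (3.08% to 17.0%) to 38.7% of the 238 on chromosome 11 (32.4% to 45.2%), leaving out the Y chromosome with its single Srf peak. Without its region from 3 to 3.1 Mb, chromosome 11 had 28.8% (21.6% to 36.8%) of 146. Chromosomes 8 and 14 had 34.95% and 34.33% with their dense blocks kept, so chromosomes were not ranked under equal trimming. The bins and blocks were chosen after their values were seen.

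**Figure D3:**
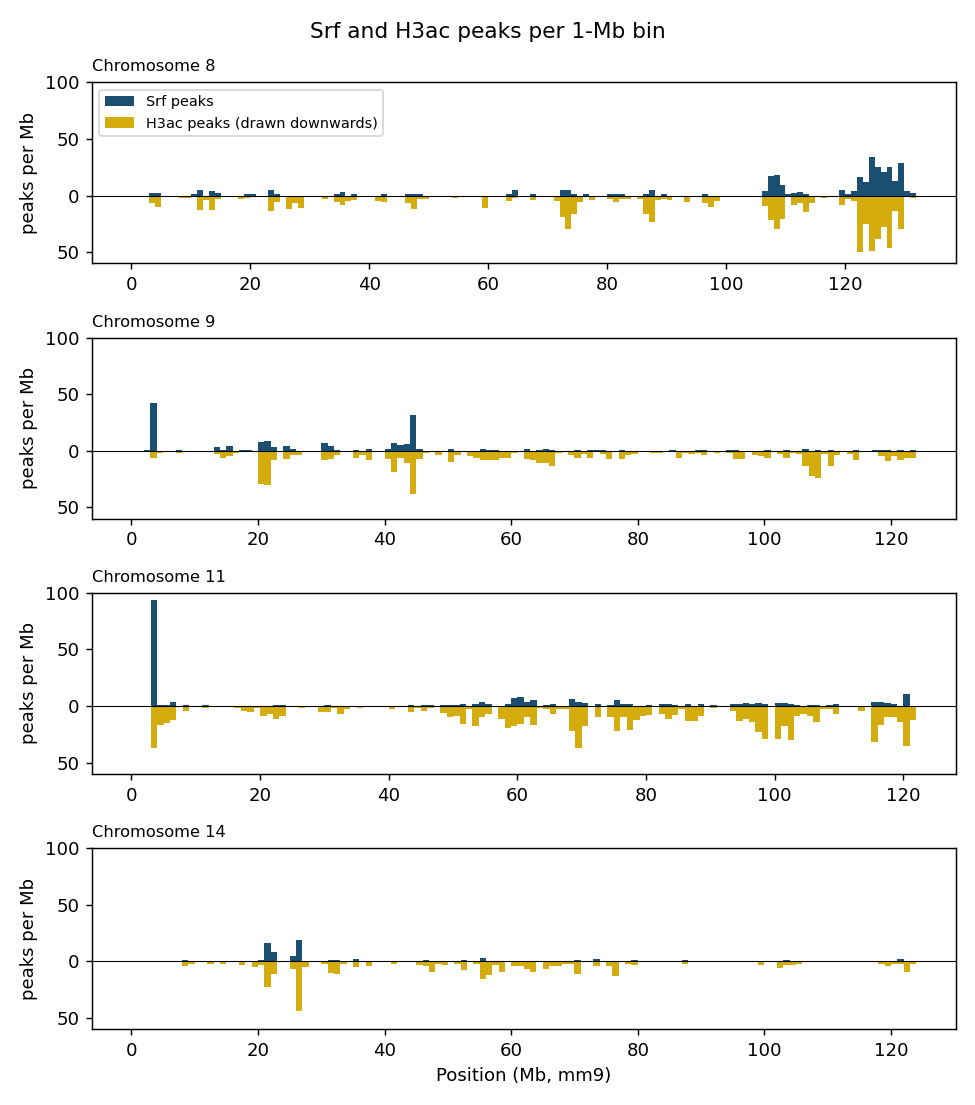
Srf peaks (upwards) and H3ac peaks (downwards) per 1-Mb bin along chromosomes 8, 9, 11 and 14, by position in mm9 (Mb). Chromosome 8 holds 175 Srf peaks from 122 to 130 Mb, and the bin that starts at 3 Mb on chromosome 11 includes the 92 Srf peaks from 3 to 3.1 Mb.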

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

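Added after seeing the data were the individual moves, the omission of dense areas, the split by identifier number, the uncounted touching ends, and the chromosome 8 and cover comparisons with all their settings. Of the alternative values, 31 kept their direction and their side of the test or, with no test, stayed in the reported interval, 33 moved in size, 1 weakened and 3 changed direction, and where no reason is given the cause was not tested. The Srf overlap share, under each definition and subset run, stayed above all 1000 displaced placements. With at least 50% of the Srf peak covered, the Srf share was 15.2% and its fold 77.5. Gaps up to 500 bp gave 56.1% and 71.4-fold (H3ac share 10.6%, 71.0-fold), and gaps up to 1000 bp gave 60.5% and 48.6-fold (H3ac 11.4%, 48.6-fold), which follows from the wider definition. Srf peaks at or above the median width gave an Srf share of 31.9%, 58.7% within 500 bp, a median gap of 177 bp and an H3ac share of 3.07%, the last because fewer Srf peaks were counted. H3ac peaks at or above the median width gave an Srf share of 17.9% (80.2-fold), an H3ac share of 6.42% (75.2-fold), 27.8% within 500 bp and a median gap of 17524 bp. The Srf peaks with the lower identifier numbers on each chromosome gave 32.5% (96.9-fold), 58.9% within 500 bp, a median gap of 166.5 bp and an H3ac share of 3.09%. These numbers fell with width, so this split largely repeats the one by Srf width. Without the dense megabases and chromosome starts the Srf share was 23.6% (98.4-fold) and the H3ac share 3.78% (97.4-fold). Individual moves in place of shifts gave 15.3-fold. Between midpoints the median distance was 532.25 bp. The Srf width difference shrank from 24 to 10 bp with gaps up to 1000 bp (permutation p = 0.0359) and to 14.5 bp without dense areas (permutation p = 0.0121), and turned to -12.5 bp (permutation p = 0.0414) when at least 50% had to be covered, a rule that favours narrow peaks. The H3ac width difference turned to -8 bp with gaps up to 1000 bp (permutation p = 0.041), and was 48 bp without dense areas (permutation p = 1e-05). The cover beside Srf midpoints over that at them was 1.32 without dense areas, 1.21 for the wider Srf peaks, 1.09 for the narrower Srf peaks and 0.937 in dense megabases, the last 2 with intervals that include 1. The chromosome 8 ratio was 1.04 without its own dense megabases and 1.23 without dense areas on all chromosomes, both with intervals that include 1, and 1.83 to 2.16 under the other 4 settings. Planned but not run were the comparisons of start sites, CArG boxes, gene lists and genes with both marks. Read depth limits both lists to an unknown degree.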

Other observations

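The tests below were chosen after the patterns were seen, except the comparison of offsets by peak width, which was fixed before its result, and to which the condition on both sides was added afterwards. At the starts of chromosomes, between 2.9 and 3.1 Mb, lay 157 Srf peaks (7.17% of the list): 92 on chromosome 11, 42 on chromosome 9, 12 on chromosome 4, 8 on chromosome 17, 2 on chromosome 18 and 1 on chromosome 3. On chromosome 11, 50 of the 92 (54.3%, exact interval 43.6% to 64.8%) overlapped an H3ac peak, and on the other chromosomes 9 of 65 (13.8%, 6.53% to 24.7%). The H3ac list held 276 peaks of 38 or 39 bp, of which 46 (16.7%) lay within 500 bp of an Srf peak, against 10.5% of other H3ac peaks. No Srf peak was narrower than 99 bp, and 96 were exactly 198 bp wide. On the 20 chromosomes tested, the number in the Srf identifier fell with width (median Spearman rho -0.936 across peaks within a chromosome, range -0.949 to -0.843), while for H3ac it was 0.174. Peaks are not independent replicates, and what the number stands for is not stated.

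The crowding of Srf peaks at chromosome starts may come from read pileups at repeated sequence that enter any library. The H3ac list had 33 peaks in these windows, 11.9 times the shifted mean, beside 292 times for Srf. Without chromosome 11 the folds were 4.69 for H3ac (10 peaks, a count reached by 11 of 1000 shifts) and 177 for Srf. H3ac peaks were also 6.67 times as dense per Mb as elsewhere in 43 bins picked past the first 4 Mb for at least 4 peaks of a random set of Srf peaks, so an excess of both marks does not single out pileups, and the explanation cannot be told apart from Srf binding there. The mm9 sequence and an input library were not used here, and no biological explanation was tested.

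The dense blocks, such as chromosome 8 from 122 to 130 Mb, could reflect only the uneven density of acetylated regions. Those 43 bins held 229 of the other Srf peaks beside 1061 H3ac peaks, and the remaining bins past 4 Mb held 758 beside 9298. The ratio of Srf to H3ac peaks was thus 2.65 times (2.25 to 3.11) higher in the picked bins, which the number of H3ac peaks alone would not give. Peaks cluster, and the interval is therefore too narrow. H3ac peaks were counted whatever their width, and wide ones were more frequent in the picked bins. The test therefore cannot exclude that Srf peaks follow the acetylated length. Extra DNA copies of these blocks in HL-1 cells remain a candidate explanation. H3ac peaks per Mb were 6.67 times as dense in the picked bins as elsewhere, as copies or a gene-rich stretch would give. But 56.1% of Srf peaks lay within 500 bp of an H3ac peak. Bins picked for Srf peaks therefore tend to hold more H3ac peaks whatever the cause, and this density cannot decide. The share of H3ac peaks under 1000 bp, which the copies were thought to raise, was lower there (85.1%, interval 82.8% to 87.2%, against 89.1% in all), but more reads can also widen peaks, so without an input library the copies cannot be told apart from clustering of Srf sites, which was not tested.

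The dip of H3ac cover at Srf midpoints was looked for in the placing of narrow H3ac peaks too. The counts here and the pairs below use only the 1585 Srf peaks outside dense megabases and chromosome starts. Their cover ratio was 1.32, against 0.937 in dense megabases. Within 100 bp of an Srf midpoint lay 106 narrow H3ac midpoints, and 134 lay at 100 to 200 bp. At 200 to 300 bp lay 229, and at 300 to 400 bp 102. If reads of the strands had been called as 2 separate blocks, the offset might be the same for Srf peaks of any width; over the 465 pairs 100 to 400 bp apart, a range that itself limits any difference, wider minus narrower was -10.5 bp (-24.25 to 9.76). That explanation also needs H3ac on both sides. This was counted over all 2190 Srf peaks, not the 1585: of the 622 with a gap of 1 to 500 bp, 17 (2.73%) had it. The H3ac list itself has no midpoints closer than 583 bp, so the count is limited by the list and the explanation cannot be told apart from others. Acetylated nucleosomes flanking a bound factor stay open as a biological explanation, untested here. The same limit of the list applies to it: 605 of the 622 had H3ac on 1 side only. The averaged profile therefore does not show H3ac on both sides of single Srf peaks.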
